A study of Mus musculus with 6 samples.

How the data were processed

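Poly(A) site sequencing (PAS-seq) measured transcript 3′ ends in 6 libraries of untreated mouse CD4+ T cells, 3 resting and 3 activated. The authors deposited whole-number counts per merged poly(A) site, with the mouse genome build mm10. Per the submitters' processing notes, TopHat2 2.0.13, Bowtie and HTSeq were used; how sites were called, merged and filtered, and whether molecular identifiers were used, is not given in the sources used here. The deposited counts were tested to be unnormalised whole numbers, and they were used without rescaling before the fits. A site overlapping several genes appears once per gene, so the 19030 lines of the table were reduced to 17806 distinct sites under 11331 gene names, of which 1113 sites (6.25%) carried more than 1 name. Every library has a lowest listed count (5, 6 and 7 in the resting and 5, 8 and 7 in the activated libraries), and smaller counts appear as 0. A further column of pooled reads over libraries that the table does not name was not used in the comparisons.

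Gene abundance was the sum of counts over all sites that carry a gene's name, with a shared site counted for each of its names. Sites were compared with the RefSeq gene table of the same genome build. Of the 19020 pairs of a site and a gene name, 73.2% lay within the gene and 17.42% up to 5000 nt past its end. A "placed" site carries a single name and lies in either of these places. Coordinates are 1-based. RefSeq gene bounds were available without 3′ UTR or intron bounds, so sites are described only by their position relative to the gene.

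Groups came from the labels, and activated cells were compared with resting cells. Genes and sites with too few counts were removed with edgeR's filterByExpr (minimum count 10), libraries were scaled by the trimmed mean of M values (TMM), and edgeR 4.0.16 quasi-likelihood F tests (robust) were run in R 4.3.3. Adjusted p-values are Benjamini-Hochberg values over all features tested, with a threshold of 0.05. CPM are edgeR's per-library scaled counts, on the TMM-scaled library sizes. For site usage, the 2 most used retained sites of each gene formed a pair, and edgeR's diffSpliceDGE tested the change of log2(distal/proximal), with the strand deciding which site is distal. A further test covered all retained sites of a gene. The mean distal share of each library was compared by an exact two-sided permutation test, whose smallest p is 0.1 with 3 libraries against 3. Gene lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over 24 lists, with an estimated correlation and fry as alternatives. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

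The groups, tests, gene lists and rule for named genes were fixed before the data were examined. The rule named the 10 highest and the 10 lowest genes past the threshold with at least 20 CPM in the higher group and no overlap between groups. In each list it named the 4 members with the smallest adjusted p, besides Il2, Il2ra, Cd69, Myc, Ifng, Klf2, Cd4 and Cd3e, and it took every cleavage and polyadenylation factor past the threshold. For site pairs it named the 10 largest shifts in each direction with at least 20 CPM over the pair in each group and no overlap of distal shares. For single sites it named the 5 highest and the 5 lowest. Some genes that the rule named are not reported here. Genes outside this rule were chosen after their values were seen; the list members named as examples beyond these 4 and the site pairs said to be so chosen belong to them. The restriction to placed sites, the raising of each listed 0 to the library's lowest listed count, and leaving out each library for the placed pairs were added after the data were seen.

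Alternatives tried were DESeq2 size factors, upper-quartile scaling, no filter, a filter of at least 5 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, limma on the log ratio (offset 0.5), the label's replicate number as a block, sites with at least 10 percent of a gene's counts, the most upstream with the most downstream site, pairs at least 200 nt apart, a median over genes, and leaving out each library. Data were simulated at the same depth, with 200 changed features per setting. Every gene and site was given 1 spread, the genes' common biological coefficient of variation of 13.4%. No library was made to differ from its group, so recovery in the real data may be lower. Of the changed genes, 41.5%, 91.5% and 97.5% were called at a 1.5-fold, 2-fold and 4-fold change. For sites the shares were 12.5%, 76.5% and 96.5%, for site pairs 7.5%, 61.0% and 97.5%, and for usage over all sites 8.0%, 56.5% and 97.5%. A 1.5-fold change was therefore often missed for site usage at this depth and simulated spread. In a simulation with 1 shifted list, that list and 0 others of the 24 were called. Genes were drawn independently there. The simulation therefore does not show how often lists are called where their genes vary together. In the real data the estimated correlation reached 0.80, for ribosome biogenesis.

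Library totals ran from 4314429 to 7007847 counts. Intervals on shares of called pairs are exact Clopper-Pearson 95% intervals over pairs, and bootstrap intervals are over genes. Both treat genes as independent and leave out the spread between libraries. Reads may not be independent molecules.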

Results

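PAS-seq, which reads the 3′ ends of polyadenylated transcripts, was applied to primary CD4+ T cells from spleen and lymph nodes of female C57BL/6J mice, purified by negative selection. There were 3 libraries of resting cells and 3 of cells activated with beads that carry antibodies against CD3, part of the T cell receptor complex, and CD28, its costimulatory receptor. All 6 were untreated samples at 0 h, and how long the cells had been activated is not given in the sources used here. The series as a whole concerns mRNA decay during T cell activation; its drug time courses and macrophage samples were not analysed here. The labels number the samples 2, 3 and 4 in each group and call them biological replicates, but do not state that each came from separate animals, so the p-values measure the spread between these samples. Counts summed to 4314429, 5944373 and 6036879 in resting replicates 2, 3 and 4, and to 4353944, 7007847 and 6100719 in activated replicates 2, 3 and 4. The 10 most used poly(A) sites held between 6.25% and 7.29% of each library. The lowest listed count stood at 0.94 to 1.24 CPM (counts scaled for library size, here and below on TMM-scaled sizes), so a listed 0 means a level below that and not the absence of a transcript.

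The groups separated along the first principal component, which held 78.9% of the variance over tested genes. Libraries of resting cells correlated with each other at 0.978 to 0.986 (Pearson's r of log2 CPM across genes, which are not independent replicates), and activated libraries at 0.965 to 0.974. Activated replicate 4 stood between the groups. Its correlation with the resting libraries was 0.926 to 0.934, against 0.859 to 0.892 for activated replicates 2 and 3. Among the resting libraries, replicate 2 held the most Il2 mRNA, 17.6 CPM against 2.05 and 1.58 CPM in replicates 3 and 4.

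**Figure D1:**
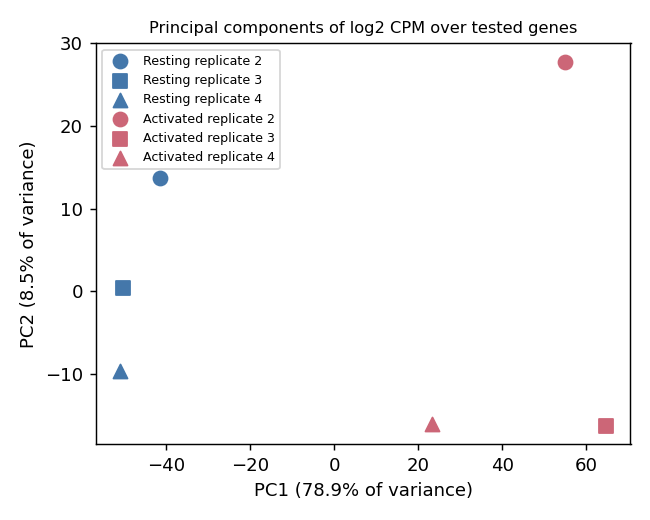
Principal components of log2 CPM over tested genes, with PC1 (78.9% of the variance) on the x axis and PC2 (8.5%) on the y axis, in arbitrary units. Each point is 1 library; activated replicate 4 lies at 23.2 on PC1, between the resting libraries at -50.9 to -41.5 and the other activated libraries at 54.9 and 64.7.

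Comparing activated with resting cells asks which transcripts change in abundance when a CD4+ T cell is stimulated through its receptor. Relative to TMM-scaled library sizes, activated cells held far more mRNA for cytokines, for T cell activation markers and for the machinery that makes ribosomes. They held less for genes of naive and quiescent T cells. No spike-in or cell count was used here, so rises and falls are relative and do not give amounts per cell. With an estimated correlation camera called 0 lists. Il2, the T cell growth factor, rose from 7.06 ± 9.09 to 462 ± 106 CPM (mean ± SD, n = 3 each). Its log2 fold change was 6.17 ± 0.68 (standard error; edgeR adjusted p = 0.000248). Klf2, a transcription factor of quiescence and lymphocyte trafficking, fell from 1616 ± 160 to 478 ± 260 CPM, a log2 fold change of -1.76 ± 0.33 (adjusted p = 0.00286). Cd3e, a subunit of the receptor complex itself, did not pass on this scale, at 276 ± 23.4 and 257 ± 17.4 CPM (log2 fold change -0.10 ± 0.10, adjusted p = 0.409).

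The edgeR quasi-likelihood test called 2985 of 10208 tested genes higher and 2740 lower at an adjusted p under 0.05. At least a 2-fold change was seen for 1171 of the higher and 777 of the lower genes. In 67.2% of tested genes the 3 resting and 3 activated libraries did not overlap, where chance gives 10%. The split depended on scaling. With upper-quartile scaling, 2254 genes were higher and 3810 lower, and the median log2 fold change of all genes moved from -0.030 to -0.216, so small changes below hold on the TMM scale.

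The 10 highest genes under the naming rule were Il17a, Il2, Lif, Irf8, Fosl1, Shmt1, Sema7a, Utf1, Hivep3 and Tbkbp1, with log2 fold changes from 5.21 to 6.28. Lif, a cytokine of the interleukin 6 family, rose from 4.84 to 272 CPM. Fosl1, a subunit of the AP-1 transcription factor, reached 33.5 CPM from 0.867 CPM. Irf8, an interferon regulatory factor, reached 1075 CPM, but its sites carry a further gene name and its counts are uncertain for that reason. For Il17a, Fosl1 and Utf1, resting libraries at a listed 0 set the fold: with each 0 raised to the lowest listed count, their log2 fold changes were 4.53, 4.50 and 4.16. Resting replicate 2 also bore on this group, since the log2 fold change of Il2 was 7.97 without it, that of Lif 6.69, that of Irf8 6.74, that of Sema7a 6.68, that of Tbkbp1 6.09, that of Hivep3 6.13 and that of Tbx21, outside these 10 genes, 5.78. Among the resting libraries Il17a and Fosl1 were listed above 0 only in replicate 2, and Utf1 only in replicate 3, so no fold is given for them without that library.

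The 10 lowest genes were Gatm, Aqp3, Tdrp, Fam78a, Fam101b, Gprc5b, Thra, S1pr1, Fbxo32 and Crxos, with log2 fold changes from -2.23 to -1.94. S1pr1, the receptor with which T cells leave lymphoid organs, fell from 749 ± 67.2 to 190 ± 126 CPM. Fbxo32, a ubiquitin ligase subunit, fell from 23.8 to 6.01 CPM, and Thra, a thyroid hormone receptor, from 26.7 to 6.60 CPM. Gatm, an enzyme of creatine synthesis, fell from 248 to 52.7 CPM, though its named site lies outside the RefSeq gene of that name, as does the only site of Crxos. These falls were steeper without activated replicate 4: the log2 fold change of S1pr1 was then -2.68, that of Gatm -2.84, that of Tdrp -3.04, that of Fam78a -2.97, that of Fam101b -2.86, that of Gprc5b -2.65, that of Thra -2.71, that of Fbxo32 -2.57 and that of Crxos -2.85.

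T cell activation markers and costimulatory genes rose together: 20 of 25 tested members were higher and 1 was lower, and 21 and 1 adjusted over the list alone. The median log2 fold change was 2.31 (camera adjusted p = 2.85e-08; adjusted p = 0.383 with an estimated correlation). Cd69, an early surface marker that retains T cells in lymphoid tissue, rose from 238 ± 47.4 to 3947 ± 1080 CPM, and Il2ra, the high-affinity subunit of the IL-2 receptor, from 69.4 ± 21.4 to 928 ± 268 CPM. Myc, a transcription factor that drives cell growth, rose from 60.3 ± 23.5 to 1561 ± 304 CPM. Further members at the smallest adjusted p were Cd40lg, the ligand with which T cells help B cells (log2 fold change 2.73), Nfkbid (3.92), a regulator of NF-kappa-B, and Egr2 (4.26), an immediate early transcription factor. Xbp1, a transcription factor of the unfolded protein response, was the lower member (log2 fold change -0.51). Ctla4, an inhibitory receptor, did not pass (log2 fold change 0.19, adjusted p = 0.269).

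Cytokines and chemokines had the highest median of the lists, 3.27, with 20 of 22 tested members higher and 0 lower, and the same counts adjusted over the list alone (camera adjusted p = 1.53e-06; adjusted p = 0.383 with an estimated correlation). Tnf rose from 21.3 ± 6.93 to 272 ± 30.8 CPM and Ifng, the signature cytokine of Th1 cells, from 7.12 ± 3.03 to 73.9 ± 27.2 CPM. Lta, Tnfsf11 and Xcl1 had log2 fold changes of 2.60, 4.55 and 3.01. Ccl1 and Il4 were listed at 0 in all 3 resting libraries and averaged 12.6 and 7.88 CPM in activated cells, at least 12.1-fold and 7.54-fold higher than the mean lowest listed level of the resting libraries, 1.05 CPM. With such genes at these limits the list's median was 3.07. Ccl5 and Ltb did not pass, at log2 fold changes of -0.43 and -0.36. With upper-quartile scaling 2 members were lower, and without resting replicate 4, activated replicate 2 or activated replicate 4 there was 1.

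Genes of naive and quiescent T cells fell as a group, with 21 of 29 tested members lower and 5 higher, over all genes and adjusted over the list alone (median log2 fold change -1.11; camera adjusted p = 0.0026; adjusted p = 0.484 with an estimated correlation). Il7r, the receptor subunit for the survival cytokine IL-7, had a log2 fold change of -1.77, Tcf7, a transcription factor of naive T cells, -1.50, and Txnip, an inhibitor of glucose uptake, -1.51. Cxcr4, a chemokine receptor, was at -0.80. The 5 higher members were Id3 (0.99), Satb1 (0.90), Btg1 (0.66), Il6st (0.38) and Btg2 (0.36). Among them, Id3 is an inhibitor of E proteins and Satb1 a chromatin organiser, and Btg1 and Btg2 are antiproliferative factors that bind the deadenylase complex. For Klf2, activated replicate 4 was the closest to the resting level, at 776 CPM against 362 and 297 CPM in activated replicates 2 and 3. Without resting replicate 3, 3 members were higher and 20 lower, and with upper-quartile scaling 3 and 22.

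The machinery of protein synthesis rose broadly, except the ribosomal proteins. Ribosome biogenesis factors were higher in 44 of 45 tested members and in 45 adjusted over the list alone, with 0 lower and a median log2 fold change of 1.97 (camera adjusted p = 2.93e-17; adjusted p = 0.383 with an estimated correlation). Nolc1, a nucleolar phosphoprotein, rose from 33.8 ± 5.16 to 251 ± 53.7 CPM, and Dkc1 and Gar1, parts of the H/ACA ribonucleoprotein that modifies ribosomal RNA, had log2 fold changes of 2.43 and 2.58. Ebna1bp2 was at 2.07. Aminoacyl-tRNA synthetases and their cofactors, which charge tRNAs, were higher in 20 of 22 members and lower in 0, as also adjusted over the list alone (median 1.63; camera adjusted p = 9.68e-08; adjusted p = 0.383 with an estimated correlation). Yars, Tars, Aimp2 and Aars had log2 fold changes of 2.81, 2.42, 1.92 and 1.99. Translation factors were higher in 31 and lower in 3 of 46 members, and 32 and 4 adjusted over the list alone (median 0.58; camera adjusted p = 5.62e-06; adjusted p = 0.383 with an estimated correlation). Eef1e1, Eif1a, Eif2s2 and Eif5a rose by 1.60 to 2.69 on the log2 scale, whereas Eif4ebp2, a repressor of cap-dependent initiation, Eif4a2 and the elongation factor Eef2 were lower (-0.84, -0.84 and -0.29). The count of lower members was 1 without resting replicate 2 or 3 or activated replicate 3, and 26 higher and 6 lower with upper-quartile scaling.

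Cytosolic ribosomal proteins did not pass as a group. Of 75 tested members, 4 were higher (Rpl12, Rps25, Rpl5 and Rps12, log2 fold changes 0.65, 0.77, 0.31 and 0.95) and 0 lower, with 2 and 0 adjusted over the list alone. Their median was -0.03 and their mean 0.02, while camera gave the direction as down (adjusted p = 0.731) and fry as up (adjusted p = 0.867). With upper-quartile scaling the median was -0.22, 2 members were higher and 21 lower, and without activated replicate 4 there were 5 in each direction. Rpl5 and Rps12 lost the call with that scaling, without resting replicate 3 and without activated replicate 2, and also Rpl5 without resting replicate 4 and Rps12 without activated replicate 3.

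Metabolic genes rose in several groups. In serine and one-carbon metabolism, which supplies nucleotide synthesis, 16 of 20 members were higher and 17 adjusted over the list alone, with 0 lower (median 1.81; camera adjusted p = 1.88e-06; adjusted p = 0.383 with an estimated correlation). Shmt1, the cytosolic serine hydroxymethyltransferase, rose from 3.74 ± 2.43 to 155 ± 43.9 CPM, and Pfas, Gart and Mthfd1, enzymes of purine and folate metabolism, had log2 fold changes of 2.29, 2.00 and 2.06. Cholesterol biosynthesis genes were higher in 14 and lower in 1 of 20 members, and the same adjusted over the list alone (median 0.76; camera adjusted p = 0.000467; adjusted p = 0.383 with an estimated correlation). Cyp51, a sterol demethylase, rose from 23.1 ± 1.35 to 130 ± 3.51 CPM, and Sqle, the squalene epoxidase, had a log2 fold change of 2.21. The lower member was Dhcr7, which completes the pathway (-0.65), and it no longer passed without resting replicate 2 or 3 or activated replicate 2 or 3. With upper-quartile scaling, 12 members were higher and 2 lower.

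Glycolysis and glucose uptake genes were higher in 9 and lower in 2 of 19 members, also adjusted over the list alone. As a list they did not pass camera but passed fry (median 0.39, camera adjusted p = 0.161, fry adjusted p = 0.00532). Their median was 0.23 without activated replicate 2 or 3 and 0.63 without activated replicate 4. Slc16a1, a lactate transporter, rose by 2.60 on the log2 scale, and Pfkfb3, Ldha and Pgam1 by 1.30, 1.32 and 1.85. The lower members were Pdk1, a kinase that inhibits pyruvate dehydrogenase (-1.36), and Ldhb (-0.67). Nuclear-encoded genes of oxidative phosphorylation were higher in 15 and lower in 2 of 39 members, and 14 and 2 adjusted over the list alone (median 0.25; camera adjusted p = 0.00501; adjusted p = 0.383 with an estimated correlation). Uqcrq and Cycs, a subunit of complex III and cytochrome c, had log2 fold changes of 1.25 and 1.45, and Uqcrfs1 and Ndufs8 0.77 and 0.64. The list had 8 higher and 5 lower members with upper-quartile scaling. Without resting replicate 2, 3 or 4 or activated replicate 2 or 3 it had 10, 10, 9, 13 and 10 higher and 1, 0, 0, 0 and 0 lower members. No mitochondrially encoded gene was listed, since the table holds 0 sites on chromosome M.

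Heat shock and integrated stress response genes were higher in 18 of 22 members and lower in 0, also adjusted over the list alone (median 1.47; camera adjusted p = 5.62e-06; adjusted p = 0.383 with an estimated correlation). Atf4, the transcription factor of the integrated stress response, rose from 515 ± 13.8 to 1417 ± 201 CPM. Hspd1, a mitochondrial chaperonin, Herpud1, a gene of the unfolded protein response, and Sesn2, a stress-inducible inhibitor of mTORC1, had log2 fold changes of 2.06, 1.82 and 3.19. The only Sesn2 site carries a further gene name, so its counts are uncertain.

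Cell cycle genes were not raised as groups. DNA replication genes were lower in 9 and higher in 2 of 34 members, and 8 and 1 adjusted over the list alone (median -0.27; camera adjusted p = 0.0227; adjusted p = 0.383 with an estimated correlation). Mcm6 and Mcm7, subunits of the replicative helicase, had log2 fold changes of -0.56 and -0.69, and Dnmt1, the maintenance DNA methyltransferase, -0.58, while the sliding clamp gene Pcna was at 0.79. Mitosis genes were lower in 7 and higher in 3 of 33 members, and 4 and 2 adjusted over the list alone. Their median was -0.43 (camera adjusted p = 0.027, adjusted p = 0.383 with an estimated correlation, fry adjusted p = 0.0512). Cenpa, the centromeric histone, was at -1.07. The 3 higher members, Ccnd2 (2.69), Cdk4 (0.78) and Cdk6 (0.84), encode a D-type cyclin and its kinases, which act at entry into the cycle, while Ccnd3, a further D-type cyclin, was at -0.95. Mki67, a proliferation marker, did not pass (log2 fold change -0.32, adjusted p = 0.119). The count of lower mitosis genes was 4, 3 and 3 without resting replicate 2, resting replicate 3 and activated replicate 3, and that of lower DNA replication genes 6 without activated replicate 2. With upper-quartile scaling, 17 DNA replication genes were lower and 1 higher, and 13 mitosis genes were lower and 2 higher.

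Interferon-stimulated genes were higher in 13 and lower in 1 of 23 members, also adjusted over the list alone (median 0.51; camera adjusted p = 0.0026; adjusted p = 0.528 with an estimated correlation). Irf1, an interferon-induced transcription factor, rose from 309 ± 46.0 to 1540 ± 287 CPM, and Socs1, a feedback inhibitor of cytokine signalling, from 26.5 ± 9.93 to 412 ± 161 CPM. Rtp4 and Igtp were at 2.03 and 2.19, the latter with uncertain counts, since both of its sites carry a further gene name. The lower member was Ifit2 (-0.87), and the antiviral genes Ifit1, Ifit3, Oasl2 and Rsad2 did not pass, at log2 fold changes of 0.50, 0.35, 0.10 and 0.08.

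Genes of the T cell receptor and of CD4 T cell identity moved both ways, with 11 of 23 higher and 8 lower, and 11 and 9 adjusted over the list alone (median 0.25, camera adjusted p = 0.331, fry adjusted p = 0.00154). Zap70, the kinase that relays the receptor signal, rose from 232 ± 5.71 to 783 ± 134 CPM, and Cd5, Ptprc and Lcp2 had log2 fold changes of 1.51, 1.14 and 2.37. Cd4 itself fell from 386 ± 16.5 to 270 ± 37.5 CPM, and the receptor subunits Cd3g and Cd247 were at -0.39 and -0.30. With upper-quartile scaling 11 members were higher and 10 lower, Cd3e among the latter (log2 fold change -0.29, adjusted p = 0.0354). Each omission of resting replicate 3 or 4 or activated replicate 2 or 3 left 5 lower members, and the median was 0.10 without activated replicate 2. Th lineage genes were higher in 6 and lower in 1 of 15 members, also adjusted over the list alone (camera adjusted p = 0.125, fry adjusted p = 0.0378). Their median was 0.51, and 0.32 without activated replicate 3. Tbx21, the Th1 master regulator T-bet, rose from 5.27 ± 3.51 to 180 ± 105 CPM, and Bcl6, the regulator of follicular helper cells, Ccr4 and Il21r were at 1.74, 2.70 and 1.19. Gata3, the Th2 regulator, did not pass (0.25, adjusted p = 0.164). Regulatory T cell markers were higher in 6 and lower in 1 of 10 members, and 6 and 2 adjusted over the list alone (median 0.43, camera adjusted p = 0.184, fry adjusted p = 0.0138). Tnfrsf1b, Gpr83, Lrrc32 and Foxp3, the regulator of this lineage, had log2 fold changes of 1.38, 3.14, 0.49 and 0.96, though both Foxp3 sites carry a further gene name, so its counts are uncertain. With upper-quartile scaling, 5 members were higher and 3 lower.

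Cleavage and polyadenylation factors, which form the 3′ ends of mRNA, were slightly higher on the TMM scale. Of 21 tested members 14 were higher and 1 lower, and 15 and 1 adjusted over the list alone (median 0.30; camera adjusted p = 0.0026; adjusted p = 0.383 with an estimated correlation). Papola, the poly(A) polymerase, rose from 81.7 ± 2.28 to 129 ± 12.1 CPM, and Cpsf2, Cstf2t and Cstf2, parts of the complexes that read the poly(A) signal and the downstream element, had log2 fold changes of 0.60, 0.46 and 0.46. Cpsf6, Cstf1, Cstf3, Pabpn1, Ppp1cb, Cpsf1, Cpsf3l, Papolg, Rbbp6 and Pcf11 lay between 0.29 and 0.46, with the only Pabpn1 site shared with a further gene name. The phosphatase subunit Ppp1ca was lower (-0.59). These small changes depended on scaling and on single libraries. With upper-quartile scaling, 6 members were higher and 1 lower, and Cpsf1, Cpsf3l, Cstf3, Pabpn1, Papolg, Pcf11, Ppp1cb and Rbbp6 no longer passed. Without resting replicate 2 or 3, 7 members were higher, and without activated replicate 2 there were 9.

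Factors of mRNA decay, the subject of the series, moved both ways, with 27 of 54 higher and 10 lower, also adjusted over the list alone (median 0.28; camera adjusted p = 0.0101; adjusted p = 0.383 with an estimated correlation). Zfp36, which binds AU-rich elements and promotes decay, rose from 200 ± 6.39 to 713 ± 41.8 CPM, and its relative Zfp36l1 from 235 ± 14.5 to 933 ± 69.6 CPM. Exosc1 and Exosc10, of the exosome, had log2 fold changes of 1.29 and 1.35. Among the lower members were Tob1 (-1.42), an adaptor of the deadenylase complex, Cnot6 (-0.77) and Cnot6l (-0.57), its catalytic subunits, and Xrn1 (-0.73), the cytoplasmic 5′ to 3′ exonuclease. With upper-quartile scaling 16 members were higher and 12 lower. Without resting replicate 2 there were 18 higher members, and without resting replicate 3 or 4 or activated replicate 2 or 3 there were 6 lower ones.

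Some markers of other cell types were present in both groups, and most of those tested did not pass. Sites were listed for only 8 of 22 B cell markers, 7 of 17 CD8 T cell and NK cell markers and 6 of 16 erythroid and platelet markers. For myeloid markers it was 19 of 28. Of 6 tested B cell markers 0 passed, over all genes or adjusted over the list alone, nor did the 4 named pass the DESeq2 Wald test or an unadjusted p under 0.05 in edgeR. Cd74 held 55.8 ± 12 and 53.7 ± 14.5 CPM (log2 fold change -0.06), and H2-Aa and Blnk were at 0.50 and 0.30. Iglc2, an immunoglobulin light chain gene, held 312 ± 170 and 249 ± 127 CPM (log2 fold change -0.33, adjusted p = 0.586, and 0.0495 with the replicate number as a block). The list's median was 0.13 (camera adjusted p = 0.8) and turned to -0.06 with upper-quartile scaling, -0.24 without resting replicate 3 and -0.03 without activated replicate 2. Of 7 CD8 T cell and NK cell markers 1 was higher (Nkg7, 1.29) and 1 lower (Klrd1, from 73.0 ± 1.24 to 30.0 ± 8.09 CPM), also adjusted over the list alone (camera adjusted p = 0.524). The median was -0.49, and -0.31 and -0.19 without resting replicate 2 and activated replicate 3. Without activated replicate 2, 2 markers of this list were lower. Cd8b1 and Gzmb did not pass, at -0.49 and 1.30, but Cd8b1 was called lower with upper-quartile scaling (-0.68, adjusted p = 0.01648), which gave 3 lower members, and also without activated replicate 4 (-0.72, adjusted p = 0.00294) or with the replicate number as a block (-0.51, adjusted p = 0.0414). Gzmb passed in 4 of 11 settings, at an adjusted p of 0.0435 without resting replicate 2, 0.00546 without activated replicate 4, 0.0412 with the replicate number as a block and 0.0411 with each listed 0 raised. Myeloid markers were lower in 4 and higher in 1 of 16 members, and 3 and 1 adjusted over the list alone (median -0.59; camera adjusted p = 0.136). Lyz2, the macrophage lysozyme, fell from 102 ± 46.8 to 33.8 ± 21.3 CPM, and Ctss from 422 ± 40.7 to 264 ± 27.0 CPM. Fcgr3 was at -2.32 (-2.83 to -1.64 with 1 library left out), while Bst2, also an interferon-stimulated gene, was at 0.43. The call of Lyz2 was lost without resting replicate 2, resting replicate 3 or activated replicate 4, that of Fcgr3 without resting replicate 3, and that of Bst2 with upper-quartile scaling. The myeloid median was -0.16, -1.20 and -0.38 without resting replicate 2, activated replicate 2 and activated replicate 3. The count of lower myeloid markers was 2, 1 and 7 without resting replicate 2, resting replicate 3 and activated replicate 2. Of 5 erythroid and platelet markers 0 passed, over all genes or adjusted over the list alone, and the 4 named passed neither the DESeq2 Wald test nor an unadjusted p under 0.05 in edgeR (median -0.30; camera adjusted p = 0.549), with Car2, Itga2b, Hbb-bt and Car1 between -0.37 and 0.31. The sign of that median turned to 0.12 without resting replicate 2, and Car2 was called lower without resting replicate 4 (-0.57, adjusted p = 0.0429). Without activated replicate 2, 1 of 6 tested markers of this list was lower. The median was -0.63 and -0.16 without activated replicates 2 and 4.

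List medians fell with upper-quartile scaling. They were 0.20 for glycolysis, 0.06 for oxidative phosphorylation, 0.12 for cleavage and polyadenylation factors, 0.09 for mRNA decay factors, 0.07 for the T cell receptor list, 0.32 for Th lineage and for interferon-stimulated genes, 0.24 for regulatory T cell markers, -0.46 for DNA replication and -0.49 for erythroid and platelet markers.

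**Figure D2:**
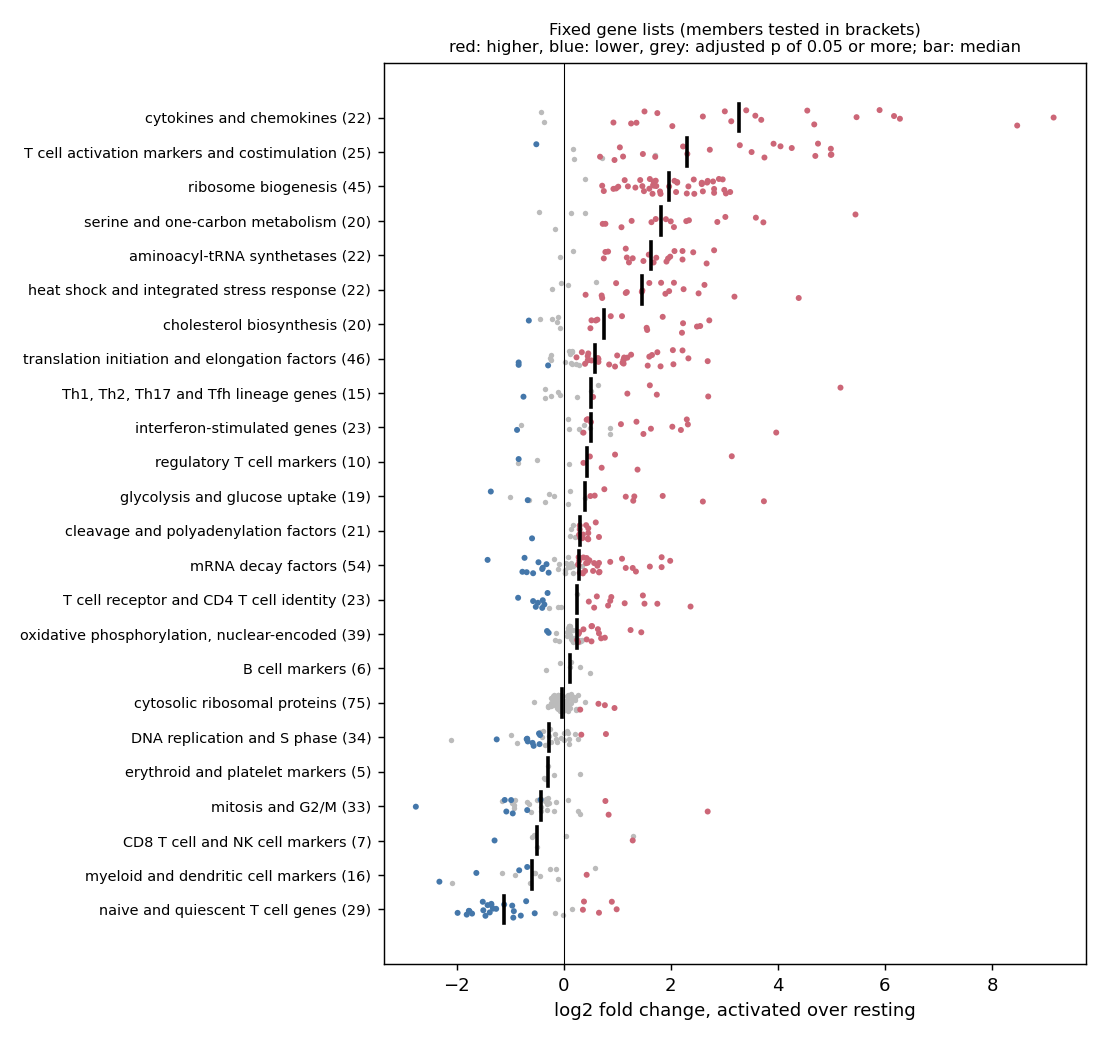
Log2 fold change of every tested member of the 24 gene lists on the x axis, with 1 list per line; red points are higher and blue points lower at an adjusted p under 0.05 on the TMM scale, grey points did not pass, and the bar is the list's median. Medians ran from -1.11 for naive and quiescent T cell genes to 3.27 for cytokines and chemokines, while those of ribosomal proteins (-0.03) and B cell markers (0.13) lay near 0, the latter turning to -0.06 with upper-quartile scaling, -0.24 without resting replicate 3 and -0.03 without activated replicate 2.

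**Figure D3:**
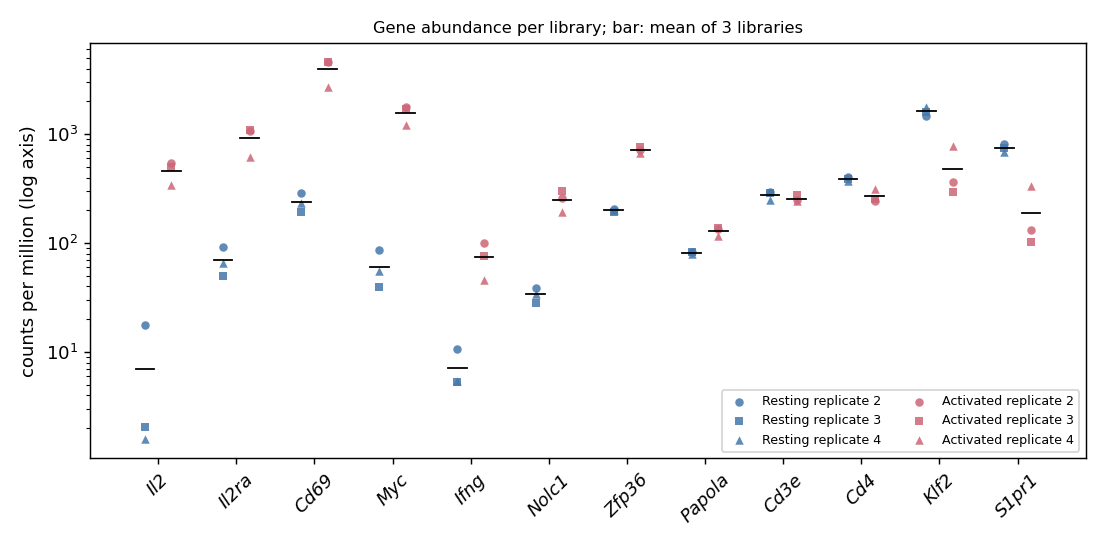
Abundance in CPM on a log axis for 12 named genes, with 1 point per library (3 resting in blue, 3 activated in red, marker shape by replicate) and a bar at the group mean. Activated replicate 4 (red triangle) lies nearest the resting libraries for Il2, Cd69 and Klf2, at 342, 2700 and 776 CPM.

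Poly(A) sites were also tested singly, since the site is the unit of the assay. The sites with the steepest rises belonged to Il17a, Il2, Lif, Shmt1 and Fosl1, with log2 fold changes from 5.47 to 6.23, and those with the steepest falls to Gatm, Aqp3, Tdrp and S1pr1, from -2.29 to -2.18. The Il17a, Shmt1 and Fosl1 sites were at a listed 0 in 2 of 3 resting libraries, and their log2 fold changes were 4.47, 4.56 and 4.45 with each 0 raised. Without resting replicate 2 all resting values of these sites are 0, so no fold is given for that setting. The Il2 site on chromosome 3 (37120837 to 37120847, minus strand) rose from 7.21 ± 9.29 to 453 ± 102 CPM. The S1pr1 site on chromosome 3 (115710572 to 115710578, minus strand) fell from 187 ± 29.7 to 41.0 ± 23.7 CPM. The 2 Tdrp sites on chromosome 8 (13952005 to 13952012 and 13952488 to 13952490) fell alike, with log2 fold changes of -2.18 and -2.21. Of 15564 tested sites, 3936 were higher and 3647 lower (edgeR), at least 2-fold for 1851 and 1208, and upper-quartile scaling gave 3612 and 4113.

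Because the assay maps where transcripts end, a further comparison asks whether activation changes which poly(A) site a gene uses. Called changes went more often toward the proximal site, the one that gives the shorter transcript. Among genes with 2 placed sites, 166 of 3123 shifted toward the proximal and 39 toward the distal site, so 81.0% of calls (74.9% to 86.1%, Clopper-Pearson) were proximal. The change for the average gene was small: the mean share of the distal site was 58.01% ± 0.19 in resting and 56.50% ± 0.22 in activated cells (SD, n = 3), a difference of -1.51 percentage points. This exceeded the spread between replicates, at an exact permutation p of 0.1, the smallest that 3 against 3 libraries allow.

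Among the largest shifts toward the proximal site, Bcl2, an inhibitor of apoptosis, used its distal site in 92.9% ± 3.20 of resting and 79.5% ± 2.56 of activated counts, with a proximal site 173995 nt upstream. For Ptbp2, a splicing regulator, the share fell from 96.6% to 89.9%, for Gtdc1 from 87.4% to 70.0%, for Gigyf2, a translational repressor, from 94.1% to 83.8%, and for Fam175a, part of a BRCA1 complex, from 93.0% to 78.9% between sites 539 nt apart. Camk2d, a calmodulin-dependent kinase, went from 96.5% to 89.97%. Adk, Magt1 and Gmfb shifted by 1.58 to 1.92 on the log2 scale while their distal share stayed above 96.6%. The proximal sites were weak in resting cells, at 0.802 (Magt1) to 4.62 CPM (Bcl2), where the mean lowest listed level was 1.05 CPM. Those of Fam175a, Gmfb, Camk2d and Adk held 1.43, 1.45, 2.13 and 2.69 CPM. Most lay far upstream: 41561 nt for Ptbp2, 222699 for Gtdc1, 93077 for Gigyf2, 26113 for Camk2d and 121779 for Adk. Under the name Magt1 the change was -0.89 without resting replicate 3, but the 2 most used sites were chosen anew in each setting. The Magt1 pair given here had distal shares of 100%, 98.76% and 98.84% in resting replicates 2, 3 and 4. Leaving out replicate 3 would not make its change smaller, so -0.89 appears to come from another pair of sites. Of these pairs, Fam175a, Magt1, Camk2d, Gmfb, Bcl2 and Gigyf2 lost the call without at least 1 library, and limma on the log ratio did not call Magt1, Bcl2 or Gigyf2.

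Toward the distal site, Nr4a1, an immediate early nuclear receptor whose 2 sites lie 278 nt apart, went from 91.6% ± 3.66 to 97.6% ± 0.228 while the counts over its pair rose from 186 to 4818 CPM. Ilkap, a phosphatase gene, went from 5.51% ± 0.738 to 14.5% ± 1.65 (log2 change 1.53 ± 0.19, adjusted p = 0.00158), and Vmp1, an autophagy gene, from 79.8% to 89.7%. Wdr33, which encodes the subunit that binds the poly(A) signal, went from 61.4% ± 7.55 to 79.8% ± 5.09, and Btg1 from 13.2% ± 3.92 to 26.3% ± 5.93. Gmeb1, Slc52a2, Zfp53 and Tonsl had log2 changes from 1.27 to 1.43. The distal sites of Zfp53 and Tonsl lie 4568 and 4149 nt past the end of the named gene and may belong to another. Except for Ilkap, limma on the log ratio or the omission of at least 1 library ended the call of each distal shift named so far. Epsti1 (log2 change 5.94) rested on listed zeros, since its log2 change was 0.16 with each 0 raised to the lowest listed count (adjusted p = 0.82).

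Several nearby pairs, chosen after their values were seen, also shifted to the proximal site. Their edgeR adjusted p ran from 0.00362 (Cpsf6 and Srsf1) to 0.0402 (Mcl1). Whether each call held with limma or with a library left out was not examined. Cpsf6, a cleavage factor that favours distal sites, used its own distal site in 83.6% ± 2.05 of resting and 67.0% ± 2.30 of activated counts, across 4365 nt on chromosome 10. Srsf1, a splicing factor, went from 35.9% ± 2.69 to 22.2% ± 0.908, and Aars, a tRNA synthetase, from 31.8% ± 2.27 to 16.9% ± 0.119. Mcl1, an inhibitor of apoptosis, went from 47.5% ± 2.62 to 38.0% ± 1.82, and Bcl11b, a T cell identity factor, from 82.9% ± 2.22 to 75.3% ± 2.61.

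**Figure D4:**
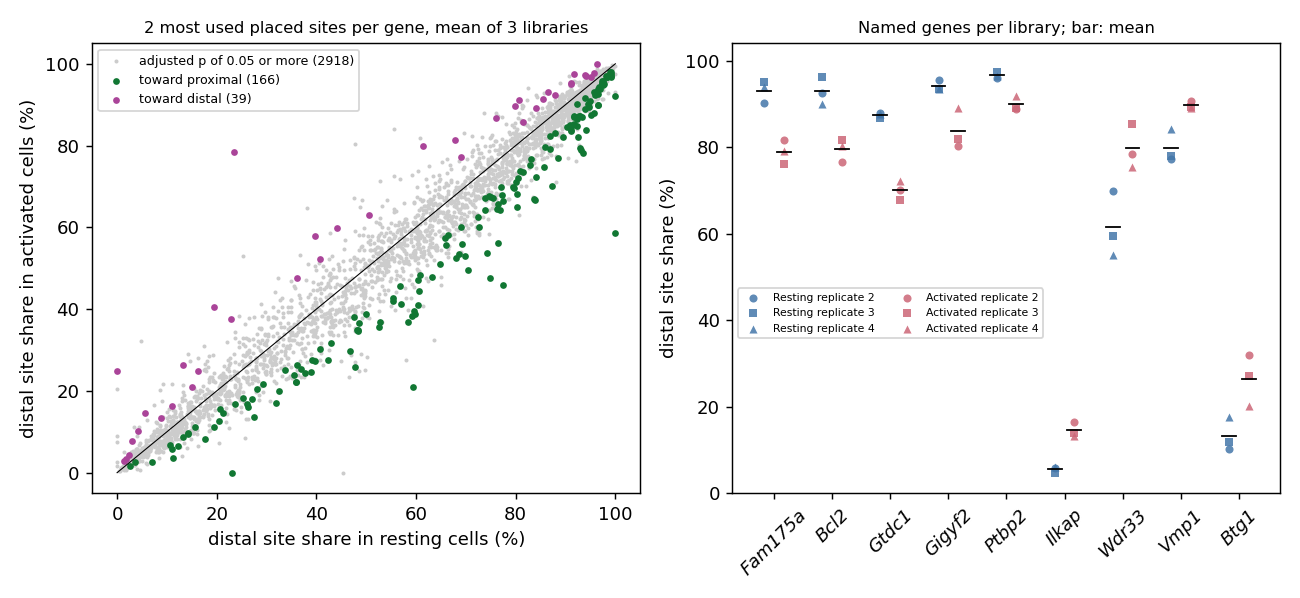
Left: share of counts at the distal of the 2 most used placed sites, in percent, in resting (x axis) against activated cells (y axis), 1 point per gene and mean of 3 libraries; 166 genes shifted to the proximal (green) and 39 to the distal site (purple). Right: the distal share per library for 9 named genes, with a bar at the mean; Bcl2 falls from 92.9% to 79.5% and Wdr33 rises from 61.4% to 79.8%.

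With every site under the gene name the table gives, 259 of 3736 pairs shifted to the proximal and 115 to the distal site, and the mean distal share was 56.78% ± 0.16 in resting and 55.43% ± 0.17 in activated cells (SD, n = 3; exact permutation p = 0.1). The test over all sites called 469 of 3736 genes, 327 of them also among the pairs. Of the 374 pairs, 136 had a site outside the named gene or shared with another name. These include many of the 10 largest shifts in each direction under the naming rule: Sssca1, Dctpp1, Dhx9, Trim56 and Wdr75 toward the proximal site, and Smg6, Pttg1, Mxi1, Bre, Fanci, Ipo4 with Tm9sf1 (the same pair of sites), Vamp1 and Rnf34 toward the distal site, whose distal site lay up to 129384 nt away. In the pairs just named, at least 1 site lies outside the named gene or carries another name. The largest shift in each direction, Nr4a2 (-5.18) toward the proximal and Epsti1 (5.94) toward the distal site, lay between 2 placed sites. Nr4a2 and Dph5 were also among the largest proximal shifts, with distal shares of 97.4% and 92.9% in activated cells, and the direction for Nr4a2 turned when each listed 0 was raised. Their calls were lost in 8 of 14 and 9 of 13 settings, and the proximal site of Dph5 was at a listed 0 in resting replicates 2 and 3. Its log2 change was -2.37, and -1.24 with each 0 raised. The calls depended on single libraries: without activated replicate 4 there were 275 proximal and 99 distal placed pairs, and without resting replicates 2, 3 and 4 or activated replicates 2 and 3 there were 61, 34, 49, 41 and 33 proximal and 24, 11, 12, 10 and 9 distal ones. limma on the log ratio called 51 and 15.

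The table types each site by its gene. Sites of protein-coding genes held 98.97% ± 0.0582 of counts in resting and 98.92% ± 0.0351 in activated cells (SD, n = 3; exact permutation p = 0.4). Sites of lincRNA genes held 0.689% and 0.739%, antisense genes 0.250% and 0.230%, and snRNA genes 0.0909% and 0.110%. The smallest exact permutation p over these 4 types was 0.1, for snRNA, and the adjusted value 0.267.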

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

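Tests of sites named for the wrong gene and of 1 share of resting RNA in every gene list were chosen after the result was seen.

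The table holds 1148 sites at 0 in all 6 libraries, and each of them has reads in the column of pooled counts, which the comparisons above do not use. These sites hold 910894 pooled reads (median 313.5 per site), and those with the most reads carry the names Cxcl2, Edn1, Cd40, Nos2 and Tlr3; the libraries behind this column are not named in the sources used here.

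Activated replicate 4 lay between the groups, at a median 0.63 of the way from the resting mean to the mean of activated replicates 2 and 3 over 1091 rising genes and 0.65 over 743 falling genes. With every library thinned to the smallest total, the median over rising genes was 0.64. Thinning leaves the expected CPM as it was, so this test could not decide whether sequencing depth was the cause. The total of activated replicate 4, 6100719 counts, lay between those of activated replicates 2 and 3, 4353944 and 7007847. Shares were unequal across 15 lists (permutation of genes, p = 1e-05, the smallest the permutations can give), from 0.47 for 10 interferon-stimulated genes to 0.86 for 7 cholesterol genes. This permutation treats the genes of a list as independent and leaves out the spread between cultures. It therefore could not decide whether a single share of resting RNA in every gene list was the only cause. Resting RNA or unresponsive cells in that culture may still contribute, since rising and falling genes differed by only -0.02 (bootstrap 95% interval -0.029 to -0.004, within the bound of 0.1 set for equal shares). A response that differs between gene groups also stays open: activation markers and ribosome biogenesis genes, compared for it, differed by 0.04 (interval -0.08 to 0.09, permutation p = 0.53), but these lists lay close together (0.68 and 0.64) while the 15 lists as a whole differed, so the bound set for that pair of lists could not exclude it.

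More genes shifted to the proximal than to the distal site. Sites named for the wrong gene are argued against as the cause, since 81.0% of called pairs (74.9% to 86.1%) were proximal among placed sites against 69.3% under all deposited names. Low counts listed as 0 are argued against by 80.2% of 232 calls (74.5% to 85.1%) with each 0 raised. Sites over 5 kb upstream were not the only source, since 81.8% (74.5% to 87.8%) of called pairs up to 5 kb apart were proximal. Proximal calls were still more frequent over 5 kb apart, at 10.6% of tested pairs against 4.4%. Introns may be shorter than 5 kb, and their bounds were not available. This cut therefore could not decide whether reads from unspliced RNA contributed. Priming inside A-rich stretches was not tested, as no genome sequence was used here, and sites in 3′ UTRs were not told from those in introns. A change of site choice on activation and a difference in decay between the isoforms may both give this pattern, and no test here separates them.

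Regrouping the 6 libraries into 3 and 3 gives 10 splits, too few for a share under 0.05, and 1 of the 10, the real one, gave the largest count each time. The real split gave 5725 genes against at most 0 in the others, 7583 sites against 0, 374 pairs against 1, 166 placed proximal pairs against 1, and 469 genes over all sites against 4.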

How the results depend on the processing

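The restriction to placed sites, the raising of listed zeros and all alternatives for placed pairs were chosen after the result was seen. Genes and sites higher and lower kept within 1.5 times their counts under every scaling, filter, test and omitted library tried, with 2254 to 3241 genes higher and 1964 to 3810 lower. Over omitted libraries the ranges were 2496 to 3241 genes higher, 1964 to 3166 lower, 3176 to 4296 sites higher, 2534 to 4329 lower, 86 to 400 genes shifted to the proximal and 63 to 193 to the distal site, 228 to 683 over all sites, 33 to 275 and 9 to 99 for placed pairs, -1.44 to -1.24 for the mean distal share, 14 to 16 gene lists, and -0.077 to -0.019 percentage points for the share of protein-coding counts. The proximal count was 134, 95, 130, 111, 86 and 400 without resting replicates 2, 3, 4 and activated replicates 2, 3, 4, and the distal count 68, 75, 65, 63 and 193 without resting 3, 4 and activated 2, 3, 4; over all sites 253, 266 and 228 were called without resting 3, activated 2 and activated 3. Fewer libraries lower these counts by construction, and the rise without activated replicate 4 goes with its place between the groups. The mean distal share moved to -1.53 with at least 5 CPM, -1.66 with the most upstream and most downstream sites and -2.49 as a median over genes, against -1.36. limma on the log ratio gave 140 proximal and 68 distal shifts, and 51 and 15 placed ones. Placed sites gave 166, 39 and 261 (over all sites) against 259, 115 and 469, with fewer pairs tested. With an estimated correlation camera called 0 lists, also at an unadjusted p under 0.05 (15 at the preset one), while fry called 18. With the replicate number as a block, 2960 and 2742 genes, 245 and 108 pairs and 16 lists were called. Whether the numbers pair the samples stays open. Deviations of resting and activated libraries of the same number correlated at 0.27, -0.01 and 0.24, and those of different numbers at -0.29 to 0.08. Directions reversed for the Nr4a2 site pair with each 0 raised (0.42, adjusted p = 0.691). With 1 library left out they reversed for Iglc2 (-0.75 to 0.09, the latter without resting replicate 2) and Cd74 (-0.29 to 0.11, with 0.11 without resting replicate 2, and 0.07 and 0.02 without activated replicates 3 and 4). They also reversed for Hbb-bt (-1.13 to 0.15, the latter without resting replicate 2) and Car1 (-0.22 to 0.84, with -0.22 without activated replicate 2 and -0.06 without resting replicate 4). The cause was not tested. Under the name Bre the value was -0.78 without activated replicate 2, but the 2 most used sites were chosen anew in each setting. The Bre pair named above had distal shares of 0%, 0% and 4.14% in resting replicates 2, 3 and 4. In activated replicates 3 and 4 they were 9.70% and 6.82%, so -0.78 appears to come from another pair of sites. Without resting replicate 4 the value was 6.98, a fitted value over a resting distal site at 0 and not a measured change. With 1 library left out, 751 results of named genes kept direction and call and 36 lost the call, and for named site pairs 170 kept it and 69 lost it. The alternative of sites annotated to the 3′ UTR was not run, as no such annotation was used here. At this depth and the simulated spread, 7.5% of simulated 1.5-fold changes were recovered for pairs.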

Other observations

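The tests of site shift against abundance and of distal calls by distance were chosen after the result was seen.

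Among the 166 placed pairs shifted to the proximal site, the proximal site itself was higher in 111 and lower in 5, while the distal site was lower in 58 and higher in 29. Among the 39 pairs shifted to the distal site, the distal site was higher in 25 and lower in 1, and the proximal site higher in 10 and lower in 11. The pairs were selected on the same counts, which favours such directions, so these numbers only describe the selected pairs. Regulators of mRNA stability were among the shifted genes: of 26 tested decay factors, Btg1, Btg2, Exosc10, Pum2 and Rc3h1 passed the test, 3 toward the proximal and 2 toward the distal site. Rpl5, the ribosomal protein gene with a called shift, used its distal site in 22.8% ± 1.97 of resting and 37.7% ± 4.85 of activated counts.

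Pairs over 5 kb apart were called proximal more often than nearer ones, 10.6% of 464 against 4.4% of 2659, a difference of 6.2 percentage points (Fisher's exact test, two-sided p = 8e-07). Distal calls were also more frequent among them, 2.8% against 1.0% (Fisher's exact test, two-sided p = 0.0047). The proximal share of the calls was 79.0% (66.8% to 88.3%) over 5 kb and 81.8% (74.5% to 87.8%) up to 5 kb.

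Genes that rose in abundance showed no larger shift toward the proximal site in these counts. Across 3123 placed pairs, Spearman's rho between the log2 fold change of the gene and the log2 change of distal over proximal use was 0.074 (permutation p = 4e-05). Both values come from the same counts of the same libraries and share their noise, which the permutation does not allow for. The sign of so weak a relation therefore stays undecided. Genes are also not independent replicates.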
